A study of Mus musculus with 2 samples.

How the data were processed

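Gene expression was measured in 2 RNA samples from mouse embryonic stem cell-derived neurons. One culture had received a lentivirus carrying green fluorescent protein (GFP) and the other a lentivirus carrying Nurr1, the nuclear receptor encoded by Nr4a2. Per the labels, virus was added at a multiplicity of infection of 10 and total RNA was taken 18 h later, labelled with biotin by a 3' in vitro transcription kit and hybridised to Affymetrix arrays. Each group was 1 sample and 1 array. The groups were taken from the labels' infection entries, and no other sample or column of values was used.

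The deposited values are probe set signal intensities on a linear scale for 45101 probe sets, of which 64 are Affymetrix control probe sets. Per the labels, the processed data were in Affymetrix's CHP format. The design text also says that gcrma values were computed for the authors' statistics. The deposited intensities are not such log2 values: they are linear, go down to 0.0535 on the GFP array and 0.0507 on the Nurr1 array, and show no floor. After the lowest and highest 2% of probe sets are dropped, the mean signal is 100.0 on both arrays, which is what scaling each whole array to one target gives. The summarisation method and its software are not given in the sources used here. The design text names the A array of the mouse set, which holds fewer probe sets than the deposited table. The annotation supplied with the table is that of the full mouse array.

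The arrays were used as scaled by the authors. Signals below 16 were raised to 16 and log2 was taken, and every difference is log2 of the Nurr1 signal minus log2 of the GFP signal on that scale. Where a signal on either array lay under 16, the difference is a lower bound on its size. Of the GFP array's probe sets, 50.3% lay below 16, and of the Nurr1 array's, 50.6%. A probe set was kept when its mean signal over both arrays was at least 15.43, the median of that mean over the 45037 probe sets other than controls. Of those, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 were not named here. The Entrez identifier was found in a RefSeq gene table (GRCm38.p6) for 34741 of the 34945, and 0 symbols changed. Each gene was represented by the probe set with the highest mean signal among those with 1 symbol, which left 11595 genes. The file names no genome build, so no coordinates are given.

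With 1 array per group there is no test across arrays and no p-value. A size of 1.6-fold (0.678 on the log2 scale), the fold part of the inclusion criterion in the series' design text, was used to count and name genes. The measurement error that 2 arrays can show was described by the SD of the differences between probe sets of the same gene. It leaves out the spread between cultures. For 32 gene lists, the median difference of the measured members was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. Such a percentile describes these 2 arrays only, and genes are not independent replicates. Lists, thresholds, filters and the naming rule were written before the data were examined, as were the alternatives unless stated otherwise. The rule named the NR4A family, the 12 genes with the largest differences each way, and up to 4 members of each list that differed at least 1.6-fold. Where no member of a list did, the 2 brightest members could be named. Other list members given with values were chosen after their values were seen. Of the symbols in the lists, 5 were updated through synonyms.

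The counting and list steps were tested on simulated data for 11595 genes, with normal noise whose spread at each level was taken from the middle of the real differences. Changed genes were drawn only from those brighter than the median gene, so the test says nothing about recovery at low signals. All simulated genes changed 2-fold or 4-fold passed the size (100.0% of 66 and of 66), against 1.5% of 68 genes changed 1.3-fold and 0.72% of 11395 unchanged genes. Such noise leaves out the tails of the real differences, so 0.72% is not a rate of false calls among the real genes. Of 200 unchanged lists of 20 genes, 4.0% fell outside the central 95% of random lists. Those lists were drawn at random from the same independent noise as the random lists, so such a share was set by construction. Genes that vary together were not simulated. All 20 lists shifted by 0.15 (100.0%) lay above that central range. The alternatives were other level filters, median centring, quantile normalization, loess centring with a span of 0.3, the mean of a gene's probe sets, probe sets without the _s_at and _x_at suffixes, a floor of 32 and a size of 2-fold. Support by 2 or more probe sets was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Array data give no read depth. The number of arrays limits the precision.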

Results

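To compare neurons carrying Nurr1 with neurons carrying a GFP control, RNA from 1 culture of each was profiled on 1 array each, 18 h after lentiviral infection at a multiplicity of infection of 10. The labels give the cells as neurons made from mouse embryonic stem cells, which the design text describes as forebrain neurons. Nurr1 is an orphan nuclear receptor of the NR4A family, known for its part in dopamine neuron development. The median probe set signal was 15.74 on the GFP array and 15.46 on the Nurr1 array, and the 75th percentiles were 104.3 and 104.1. Across the 45037 gene probe sets, the log2 signals of the arrays correlated with a Pearson r of 0.9948. Neither group had replicates, so no value below has a replicate error, and none of the differences could be tested against the variation between cultures.

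Nr4a2, the gene delivered by the Nurr1 virus, was higher on the Nurr1 array. Its brightest probe set read 37.4 with GFP and 125.4 with Nurr1, a 3.35-fold difference (log2 1.75). A second probe set read 26.18 with GFP and 127.4 with Nurr1 (log2 2.28), and another 18.54 and 73.03 (log2 1.98). The remaining probe set past the level filter read 36.98 and 45.04, a log2 difference of 0.28. The last 2 of the 6 Nr4a2 probe sets lay below 16 on both arrays. The difference thus had the direction of the sample labels on all 4 probe sets past the filter, 3 of them past 1.6-fold. The positions of the probe sets relative to the delivered sequence were not analysed here. Whether the smaller difference and the 2 probe sets below 16 count against the labels therefore cannot be told. The other family members differed less: Nr4a1 read 92.05 and 98.01 (log2 0.09), and Nr4a3 read 17.51 and 23.66 (log2 0.43).

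**Figure D1:**
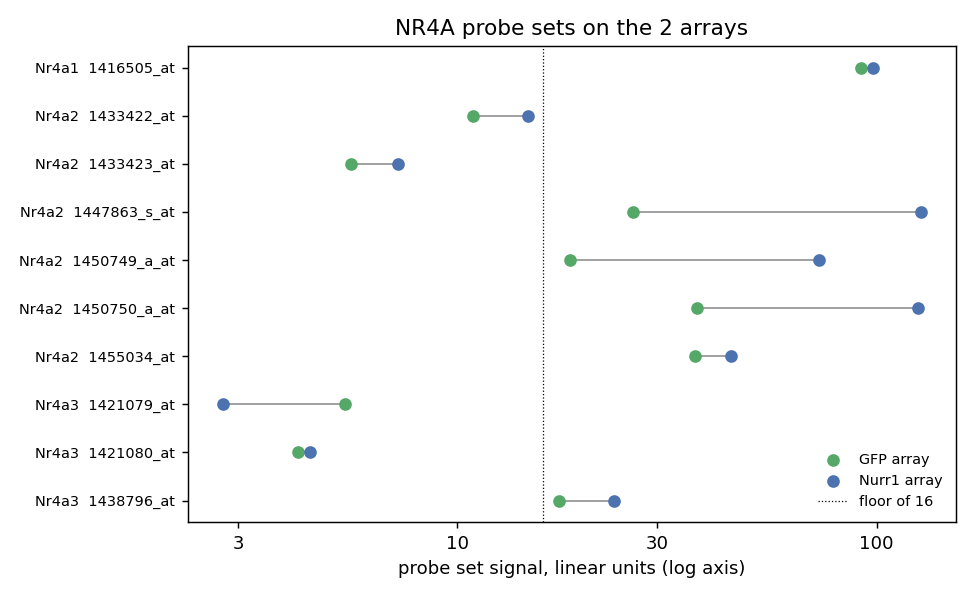
Signal of each NR4A probe set (linear units on a log axis) on the GFP array (green) and the Nurr1 array (blue), with a dotted line at the floor of 16 used before taking log2. For Nr4a2, 3 probe sets lie between 73.03 and 127.4 on the Nurr1 array and between 18.54 and 37.4 on the GFP array.

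Of 11595 genes, each read on its brightest probe set, 91 were at least 1.6-fold higher with Nurr1 and 111 at least 1.6-fold lower, together 1.74%. The other probe sets of these genes gave more higher than lower readings, 281 (3.24%) and 125 (1.44%) of 8685. On the brightest probe sets, the largest positive differences besides Nr4a2 were those of Crim1, a transmembrane protein that binds bone morphogenetic proteins (9.733 against 57.29, at least 3.58-fold), and Hyls1, a centriolar protein (16.3 against 55.56, 3.41-fold). They were followed by Cnksr2, a scaffold of Ras signalling (2.54-fold), the semaphorin Sema5a (2.41-fold), the heparan sulphate proteoglycan Sdc4 (2.37-fold), the sulphurtransferase Mpst (2.35-fold) and Scyl2 (2.35-fold). Ankhd1 (2.28-fold), the non-coding Gdap10 (2.25-fold), the proteoglycan Srgn (2.24-fold) and the cohesin loader Nipbl (294.4 against 646.8, 2.2-fold) completed the 12 highest.

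The largest negative difference was that of the nucleoside diphosphate kinase Nme1, which read 1670 with GFP and 565.2 with Nurr1 (log2 -1.56). Its other probe set differed by 0.11 in the opposite direction. Ighmbp2, a helicase, was at least 2.86-fold lower with Nurr1, 4930563E22Rik 2.74-fold, the pseudogene Macroh2a3 2.54-fold, Ccdc180 at least 2.51-fold and Spry4, an inhibitor of receptor tyrosine kinase signalling, 2.49-fold. The orphan receptor gene Gpr27 was 2.3-fold lower, Kcnmb4os2 at least 2.29-fold, Lce3b 2.23-fold, the glutamate transporter gene Slc1a3 2.22-fold, Hinfp, a regulator of histone genes, 2.19-fold and Zfp235 2.18-fold. Probe sets ending in _x_at, among them those of Nme1, Macroh2a3 and Lce3b, can match related sequences, so these values are uncertain.

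**Figure D2:**
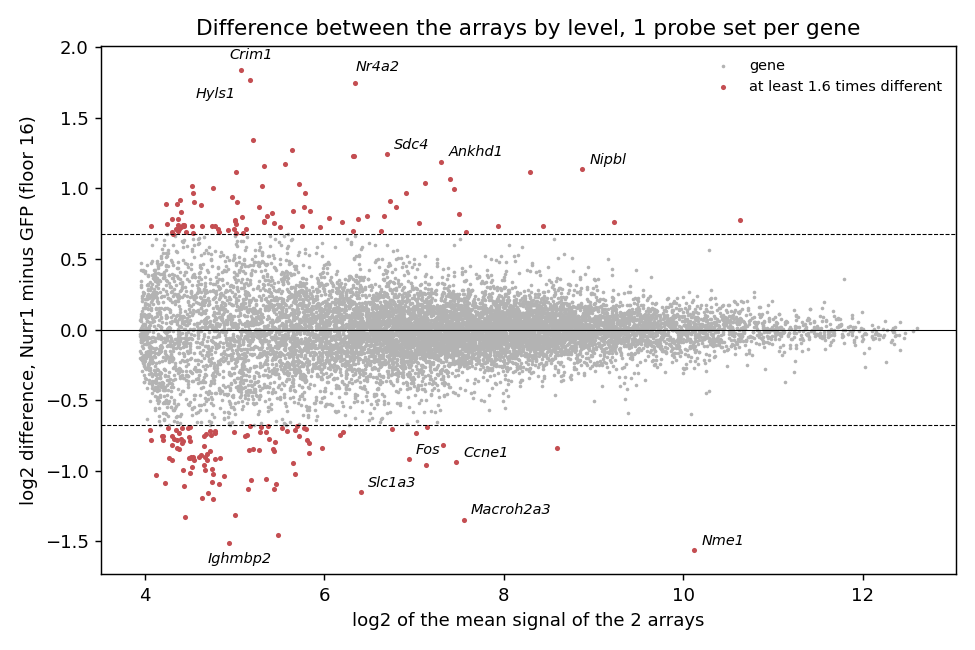
Log2 difference (Nurr1 minus GFP, after a floor of 16) of each of the 11595 genes against log2 of its mean signal over both arrays; red points lie outside the dashed lines at 1.6-fold and selected genes are named. The scatter narrows with level, and most red points lie at low signals.

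Most of these differences lay at low signals, and most of the genes had no second probe set past the filter to compare. Of the genes past 1.6-fold, 73 of the 91 higher and 101 of the 111 lower had a mean signal under 100. The SD of the differences was 0.344 among the 2899 dimmest genes and 0.129 among the 2899 brightest. Probe sets of the same gene differed from each other by an SD of 0.261 (log2, 5303 genes), and across genes the differences of the 2 brightest probe sets correlated with a Pearson r of 0.119 and a Spearman rho of 0.118. Among the 32 higher genes with a second probe set, 17 second probe sets also read higher and 1 of them, that of Nr4a2, by 1.6-fold. Among the 23 such lower genes, 14 second probe sets read lower, 3 of them by 1.6-fold. Of single genes, Slc1a3 had 3 other probe sets past the filter, which differed by 0.14, -0.07 and -0.04. Likewise, the other probe sets of Sdc4 and Scyl2 differed by -0.08 and -0.03, and the 3 others of Ankhd1 by 0.05, -0.17 and 0.02. The other probe set of 4930563E22Rik read 46.14 and 41.44 (average of both, log2 -0.80). The other probe set of Hinfp differed by 0.50, against its negative difference, and the other 2 of Sema5a by 0.32 and -0.04. By contrast, Crim1 was higher on both its probe sets past the filter, by at least 1.84 and 0.66, and Nipbl was past 1.6-fold on 2 of 4. With a floor of 32, which shrinks the differences of dim genes by construction, 7 of the 12 lowest genes did not reach 1.6-fold (Gpr27 -0.24, Kcnmb4os2 -0.20, Lce3b -0.17, Ccdc180 -0.33, Spry4 -0.51, Ighmbp2 -0.51 and Zfp235 -0.60), against 0 of the 12 highest, nor did Dhrs3, Gadd45b, Syn1, Cd68 and Dbh. With averaged probe sets, 4 of the 12 highest (Sema5a, Sdc4, Scyl2 and Ankhd1) and 2 of the 12 lowest (Slc1a3 and Hinfp) did not, nor did Gadd45b, Cux2, Ccne1 and Egln3. Without _s_at and _x_at probe sets, Nme1, Gadd45b, Ccne1 and Adm did not. Macroh2a3, Lce3b and Dbh, each read on an _x_at probe set, could not be measured in that setting.

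Genes of cell protection and stress showed few differences. None of the 29 measured genes of oxidative stress defence reached 1.6-fold, and their median difference was -0.02, at percentile 28.53 of matched random lists. The glutamate-cysteine ligase subunit Gclm (205.7 and 260.2, log2 0.34) and the sestrin Sesn1 (167.6 and 213.8, log2 0.35) had the highest values in that list, the superoxide dismutase Sod1 read 1241 and 1406 (log2 0.18), and Hmox1, which degrades haem, had the lowest value (134.6 and 112.3, log2 -0.26). No member was past 1.6-fold among 20 pro-apoptotic genes (median -0.07, percentile 8.71), 15 anti-apoptotic genes (0.03, percentile 78.35), 22 p53 targets (-0.03, percentile 22.49), 30 genes of the unfolded protein and integrated stress responses (-0.03, percentile 12.9) or 15 heat shock genes (0.03, percentile 85.86). The 16 neurotrophic and growth factor genes had a median of -0.09 (percentile 11.94) but a mean of 0.008, with 0 past 1.6-fold. Of 26 genes induced by CREB or as immediate early genes, 2 were lower by at least 1.6-fold, the transcription factor gene Fos (160.6 and 84.95, 1.89-fold) and Gadd45b (32.15 and 19.26, 1.67-fold), and 0 were higher. The list's median was -0.05 (percentile 18.88), but -0.12 when all probe sets of a gene were averaged, below the central 95% of random lists (percentile 0.86). The second probe set of Gadd45b differed by -0.08. For genes that respond to virus or inflammation, the 19 interferon response genes had a median of -0.10 (percentile 10.94) and the 10 NF-kB genes 0.01 (percentile 58.88), with 0 past 1.6-fold in both lists.

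Dopamine neuron genes, the class Nurr1 is best known to control, had a median difference of 0.06 over 18 measured genes of 25 (percentile 92.12), with 11 above 0 and 7 below, and 0 of them reached 1.6-fold. Slc6a3, Drd2 and Pitx3 were among the members not measured, so these values say nothing about them. The list lay above the central 95% of random lists when all probe sets of a gene were averaged (median 0.08, percentile 97.65). It lay at percentiles 51.43 with no level filter (median 0.0) and 52.68 with a floor of 32. In these last settings, members below the floor on both arrays read exactly 0. That draws a percentile to the middle by construction, so both values say little about the list. Th, the rate-limiting enzyme of dopamine synthesis, read 20.28 with GFP and 23.91 with Nurr1 (log2 0.24), the vesicular monoamine transporter gene Slc18a2 15.55 and 19.29 (log2 0.27), Ddc 59.97 and 63.38 (log2 0.08), and Lmx1b 42.73 and 61.7 (log2 0.53). The lowest values were those of Dlk1 (83.68 and 71.74, log2 -0.22), Bdnf (-0.21), Lmx1a (-0.18) and Ptpru (-0.16). Pan-neuronal genes had a median of 0.01 over 28 genes (percentile 67.22) but a mean of -0.03. Tubb3, a neuronal tubulin, read 652.4 and 654.8, and only the synaptic vesicle gene Syn1 was past the size (44.6 and 27.72, 1.61-fold lower). Syn1 did not reach 1.6-fold with median centring or loess centring. The 15 measured forebrain glutamatergic genes of 30 had a median of 0.02 (percentile 69.54) and a mean of -0.01, with Cux2 1.83-fold lower on its brightest probe set and 0.41 higher on another. The 5 measured GABAergic genes of 24 had a median of -0.18 (percentile 5.72), the 13 voltage-gated channel genes 0.10 (percentile 88.36), and the 28 axon guidance and adhesion genes 0.04 (percentile 92.38), with 0 past 1.6-fold in these 3 lists. The axon guidance list lay at percentile 97.56 with a floor of 32.

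Markers of other cell types had medians within 0.1 of 0. Radial glia and progenitor markers had a median of -0.01 (18 genes, percentile 42.62), astrocyte markers 0.08 (11 genes, percentile 93.52), oligodendrocyte lineage markers 0.09 (7 genes, percentile 86.21), mesenchymal markers -0.003 (20 genes, percentile 53.16), endothelial markers 0.04 (4 genes, percentile 65.93), microglial and haematopoietic markers 0.04 (3 genes, percentile 62.28), neural crest and peripheral neuron markers -0.04 (10 genes, percentile 46.39) and proliferation genes 0.01 (31 genes, percentile 77.61). The means of the astrocyte and proliferation lists were both -0.02, opposite in sign to their medians. The astrocyte list lay above the central 95% of random lists with no level filter (percentile 99.85) and with a stricter one (97.94). Single members past 1.6-fold were Slc1a3, described above, Cd68 (21.38 and 35.04, 1.64-fold higher), Dbh (33.98 and 3.43, at least 2.12-fold lower) and the cyclin gene Ccne1 (232.3 and 121.1, 1.92-fold lower). The other probe set of Ccne1 differed by -0.11. The 16 measured pluripotency markers had a median of 0.10 (percentile 97.59), with 11 above 0 and 5 below. Tdgf1 was 1.66-fold higher (46.74 and 77.54) and Pou5f1 read 320.3 and 408.4 (log2 0.35), whereas Utf1 (57.38 and 38.59, log2 -0.57), Dppa3 (30.43 and 25.68) and Klf5 (200.7 and 173.8) read lower.

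The metabolic gene lists differed by small amounts and in both directions. Genes of glycolysis and the response to low oxygen had a median difference of 0.09 over 22 genes, at percentile 99.94 of matched random lists, with 18 above 0 and 4 below. The peptide hormone gene Adm was 2.02-fold higher with Nurr1 (26.12 and 52.86) and the prolyl hydroxylase gene Egln3 1.75-fold (73.91 and 129), and both were also higher on their other probe sets, by 0.36 and 0.41. Egln3 did not reach 1.6-fold with averaged probe sets, nor Adm without _s_at and _x_at probe sets. The other 20 did not reach 1.6-fold. The highest of them were the phosphofructokinase gene Pfkp (log2 0.52), P4ha1 (0.48), Hk2 (0.42) and the mitophagy receptor gene Bnip3 (698.6 and 902.7, log2 0.37). The 4 below 0 were Higd1a (-0.10), Vegfa (-0.07), Hk1 (-0.07) and Slc2a3 (-0.05). Slc2a1 (0.02) lay close to 0. Ldha (3816 on both arrays) and Pkm (3276 on both) hardly differed, though both count as above 0. The 36 genes of the mitochondrial respiratory chain had a median of -0.04 (percentile 1.59), with 25 below 0, and 0 reached 1.6-fold. The 13 retinoid receptor and metabolism genes had a median of -0.18 (percentile 0.68), with 9 below 0. The retinal reductase gene Dhrs3 was at least 1.62-fold lower (26 and 12.19), and the receptor gene Rarg and the retinoic acid synthesis gene Aldh1a2 differed by -0.58 and -0.55. Cholesterol synthesis genes had a median of 0.04 (20 genes, percentile 94.21), cytosolic ribosomal protein genes -0.03 (20 genes, percentile 12.1) and reference genes 0.01 with a mean of -0.002 (10 genes, percentile 59.54), with 0 past 1.6-fold in these 3 lists.

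Of the 32 lists, 5 lay outside the central 95% of random lists, where 1.6 would if lists were random draws of genes. Genes of a real list can vary together, so 1.6 is not the number to expect here. The 5 were the NR4A family (median 0.43, percentile 99.29, a list of 3 genes that contains the delivered one), glycolysis and low oxygen, pluripotency, the respiratory chain and the retinoid genes. For 20 lists no member reached 1.6-fold. Median centring shifts a list and its random lists almost alike and is not counted here. Glycolysis and low oxygen stayed outside in 8 of 8 alternative settings, the NR4A family in 6 of 7, the respiratory chain in 6 of 8, and the retinoid and pluripotency lists in 5 of 8 each. Retinoid genes lay at percentile 53.41 with a floor of 32, the respiratory chain at 28.92 with averaged probe sets and pluripotency at 81.87 with a stricter level filter, their largest moves. The retinoid median was then 0.0, because the floor of 32 sets dim members to exactly 0 by construction, so that move says little.

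**Figure D3:**
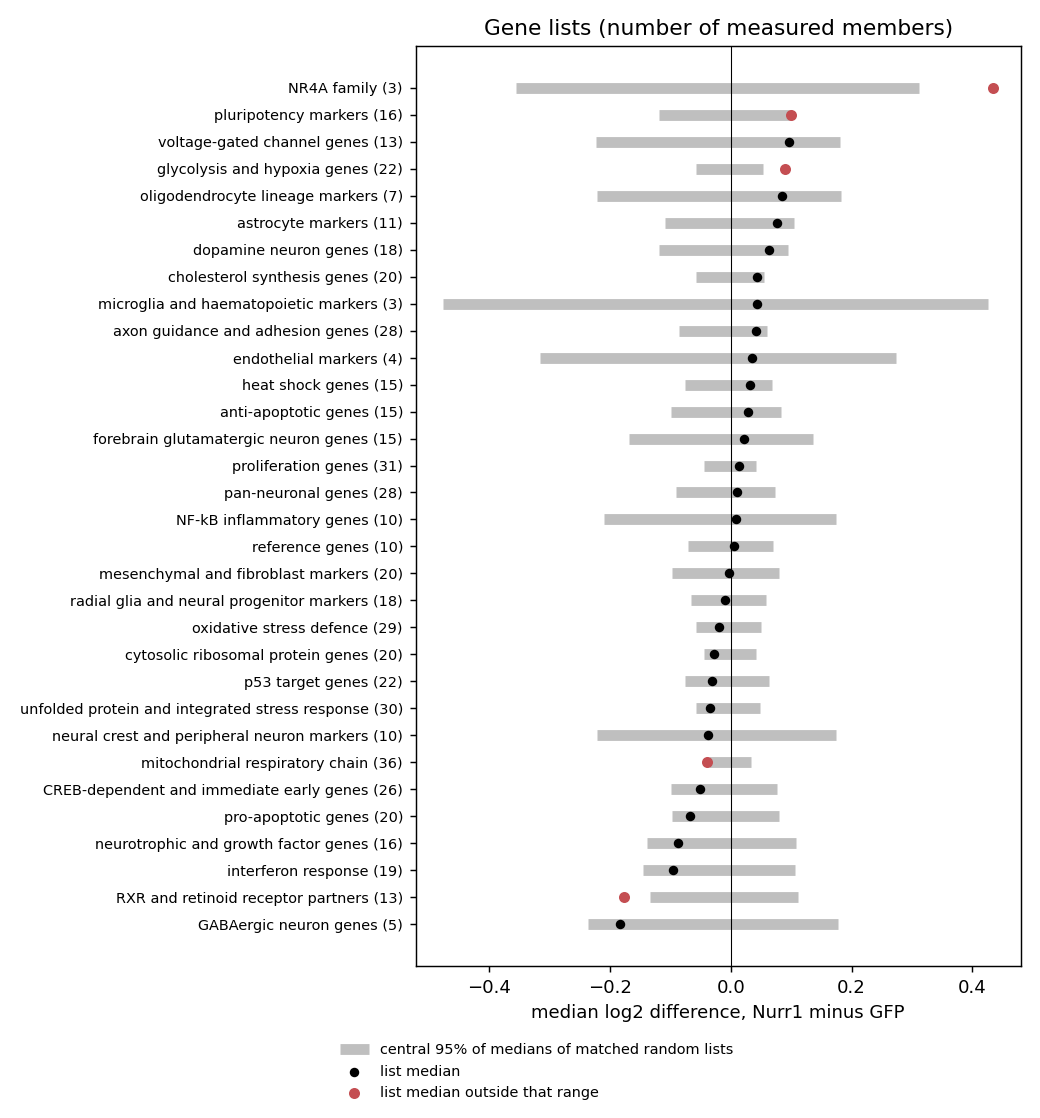
Median log2 difference (Nurr1 minus GFP) of each of the 32 gene lists (points, with the number of measured members in brackets) and the central 95% of medians of 10000 level-matched random lists (grey bars). Red points mark the 5 lists outside that range, of which glycolysis and hypoxia genes lie at 0.09 and retinoid genes at -0.18.

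Control probe sets gave the technical difference between the hybridisations. The 18 probe sets for hybridisation controls, added to the labelled sample, had a median difference of -0.01 (range -0.13 to 0.18). The 24 probe sets for poly-A control RNAs of Bacillus subtilis, made to be added before labelling, all read lower on the Nurr1 array, with a median of -0.34 and a range of -0.68 to -0.08. The 3 probe sets for 18S ribosomal RNA, all dim, read 20.83, 23.73 and 25.36 with GFP and 34.01, 31.87 and 51.97 with Nurr1 (log2 0.71, 0.43 and 1.04). The ratio of 3' to 5' probe set signals, a measure of RNA integrity, was 1.4 with GFP and 1.3 with Nurr1 for Actb, 0.851 and 0.87 for Gapdh, and 3.9 and 3.28 for Tfrc. The 5' probe set of Tfrc lay near the floor (16.54 and 21.65).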

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

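The 91 higher and 111 lower genes became 16 and 10 with a stricter level filter that left 7099 genes, 45 and 35 with a floor of 32, and 20 and 24 at a size of 2-fold; these settings remove dim genes or small differences by construction. The split moved from 45.0% higher to 61.5% with the stricter filter and 56.2% with the floor of 32. In an alternative chosen after seeing the data, 30 genes had 2 or more probe sets at least 1.6-fold higher and 6 had 2 or more lower. The remaining planned settings left 84 to 99 genes higher and 98 to 117 lower. Dropping the level filter, or setting it on the higher array, moved neither count, so these 2 settings say nothing about the stability of the counts. The averaged probe sets kept 64 of the 91 and 93 of the 111 genes, quantile normalization 90 and 111, and median centring 91 and 98. By probe set, Nr4a2 also gave 2.28, 0.28 and, on 2 probe sets below the floor, 0.0 and 0.0. Nme1 reversed from -1.56 to 0.11 without _s_at and _x_at probe sets, where its other probe set stood in. Of 291 values for 36 genes named for their size or family, 255 moved by less than 0.261, the SD between probe sets of one gene, 35 by more, and 1 (Nme1) reversed. The 255 include values that could not move. A level filter leaves a gene's brightest probe set in place, and averaging cannot move a gene with 1 probe set past the filter. The 255 therefore overstate how stable the named genes are. Of 280 list medians, 252 moved by less than the SD of random medians and 28 by more. In 18 the sign changed, 4 of them among those that moved by more: with the stricter filter interferon response (-0.10 to 0.04), pro-apoptotic (-0.07 to 0.04) and oligodendrocyte genes (0.09 to -0.02), and with quantile normalization ribosomal protein genes (-0.03 to 0.001). None of the 18 was of the 5 lists outside the central 95%. The percentile of glycolysis and low oxygen genes ranged from 99.1 to 100 over 8 settings (median centring, which can hardly move a percentile, left out), that of the NR4A family from 91.14 (floor of 32) to 99.66 over 7, pluripotency from 81.87 to 99.17, the respiratory chain from 1.52 to 28.92 and retinoid genes from 0.51 to 53.41. Pluripotency fell inside the central 95% with the stricter filter (81.87), averaged probe sets (97.01) and the filter on the higher array (96.97), the respiratory chain with averaged probe sets (28.92) and without _s_at and _x_at probe sets (4.04), and retinoid genes with a floor of 32 (53.41), the stricter filter (16.3) and no filter (3.97). The 53.41 came with a median of 0.0, since a floor of 32 sets dim members to 0 by construction. Averaged probe sets put immediate early genes (0.86, from 18.88) and dopamine neuron genes (97.65, from 92.12) outside. No paired analysis was possible because each group had 1 array and the labels pair none, and no replicate could be left out for the same reason. Low signal over background limits the dim genes, whose differences had an SD of 0.344 against 0.129 for the brightest. The cause of the other moves was not tested.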

Other observations

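The tests by 3' to 5' ratios, both tests of the poly-A controls and the count of genes with 2 or more probe sets were chosen only after their results were seen, and the test of nuclear transcripts on dimmer probe sets after that on the brightest. Genes of regional and stage identity were also picked after their values were seen. The genes picked for floor plate and ventral midbrain gave clear signals. Lmx1a, which specifies midbrain dopamine neurons, read 1128 with GFP and 994.2 with Nurr1, and Foxa2 579.9 and 616.1. Otx2 read 673.5 and 645.8, and the morphogen gene Shh 1344 and 1098 on its brighter probe set. Members of the dopamine neuron list not picked here were dimmer, such as En1 (56.34 and 60.08), En2 (66.88 and 74.03) and Lmx1b (42.73 and 61.7). Genes of stem and dividing cells were also measured, with Sox2 at 1399 and 1480, Lin28a at 1409 and 1342, Pou5f1 at 320.3 and 408.4, and the topoisomerase gene Top2a at 2211 and 2308. All probe sets of 5 cortical genes (Emx1, Emx2, Tbr1, Neurod6 and Slc17a7) lay below the floor of 16 on both arrays. Other genes of the forebrain glutamatergic list did not: 15 of its 30 passed the level filter. They ranged from Cux1 (214.9 and 233.3), Pax6 (99.23 and 103.5) and Eomes (77.4 and 80.1) to the dim Gria2 (20.33 and 15.55). The neuronal genes Stmn2 (802.9 and 803.1) and Map2 (317.6 and 337.9) also gave clear signals. Other members of the pan-neuronal list ranged from Nefl (482.9 and 548.9) to the dim Syp (42.94 and 31.73), Rbfox3 (21.58 and 24.19) and Nefh (21.93 and 19.56). The design text describes forebrain neurons. Signals of different probe sets cannot be compared as amounts, and the makeup of the cultures was not tested.

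The genes of glycolysis and low oxygen lay above random lists in all 8 alternative settings that could move the percentile. Error of the chosen probe sets was argued against by the 14 members with a second probe set, of which 13 read higher there too (median 0.115, percentile 99.3), and a trend with gene length (Spearman rho 0.116 over all genes) by the list's percentile of 99.93 among lists also matched on length. A second list of low oxygen response genes, chosen after the first list's result was known but before its own values were seen, shared no member with it and had 22 of 26 genes above 0, among them the glycogen gene Gbe1 (0.64), Ppp1r3c (0.76), Egln1 (0.32) and Ddit4 (0.20), which the unfolded protein list also holds. Its median of 0.20 lay above all 10000 random lists (percentile 100), so a higher level of hypoxia-response transcripts in the Nurr1 culture is a hypothesis these values are consistent with. Whether Nurr1 or a difference in density, medium or handling of the dishes may lie behind it was not tested, because each condition was 1 culture.

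By probe set, 30 genes had 2 or more readings at least 1.6-fold higher with Nurr1 and 6 had 2 or more lower. They include the stress gene Ndrg1 (3 of 5 probe sets), Stc2, the helicase gene Ddx6, Gas2l3, Rbm25, Rbm39, Srrm2, Thoc2 and the nuclear RNA Malat1, and among the 30 the brightest probe set was past 1.6-fold only for Kif5b, Nipbl and Nr4a2. Independent error of single probe sets was argued against by 1000 shuffles among probe sets of similar level, which gave a median of 5, an upper end of the central 95% of 9.0 and at most 14 such higher genes, and 2, 5 and 7 such lower genes. The 6 lower genes lay above that upper end but not above the highest. The shuffles took probe sets of a gene as separate. Some may read the same sequence, such as 2 of Rbm39 (1.06 and 1.064), which was not checked. They also pooled brightest and other probe sets, of which 0.78% and 3.24% read higher, which can lower the shuffled counts. For more nuclear RNA in the Nurr1 sample, 20 transcripts listed as nuclear lay at percentile 51.34 on their brightest probe sets. The pattern is mostly absent there. The listed transcripts lay at 26.14 on 38 other probe sets (14 genes, median -0.03, bootstrap 95% range -0.10 to 0.10). Both results met the bounds set, before they were seen, for this explanation not to hold. The first cannot decide, because the brightest probe sets mostly lack the pattern. The second argues against a general rise of the listed transcripts on those other probe sets. The list also holds Gas5, Snhg1 and Ogt, and whether these stayed in the nucleus was not measured. More nuclear RNA may still contribute, because the list left out Malat1, whose values were already known (0.96 and 1.89 on 2 dim probe sets, -0.19 on its brightest). Single other probe sets went both ways, such as those of Pnisr (0.94 and 0.67), Rian (0.48) and Pvt1 (-0.59). Less degraded RNA in the Nurr1 sample may also contribute, and the 2 explanations cannot be told apart. The 3' to 5' ratio was lower with Nurr1 in 2 of 3 genes, Actb and Tfrc. The 5' probe set of Tfrc read 16.54 and 21.65, too near the floor for its ratio to decide.

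The poly-A controls read lower on the Nurr1 array in 24 of 24 probe sets. Brightness or scaling of the array was argued against by the hybridisation controls, with a median of -0.006. The medians of the 4 control RNAs lay within 0.102 of each other, from -0.43 for phe to -0.32 for dap. Less control RNA added per amount of sample RNA may give this, and so may more mRNA per total RNA in the Nurr1 culture. These cannot be told apart: both predict an equal shift of all 4, and the 3 probe sets for 18S ribosomal RNA, which read higher with Nurr1 (0.71, 0.43 and 1.04) and so run against more mRNA per total RNA, are too near the floor to decide.

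Probe sets without a listed symbol gave 52 readings at least 1.6-fold higher and 41 lower of 1694 past the level filter.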
